A study of Mus musculus with 104 samples.

How the data were processed

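RNA was extracted from dissected cerebral cortex with RNeasy kits, and stranded TruSeq libraries were sequenced from mice of 13 lines, 4 females and 4 males per line, per the labels' protocols. The labels also give a plate (96 libraries on plate 1 and 8 on plate 2) and a well for each library. The submitters' processing notes name STAR 2.7.3a, HTSeq 0.10.0 and the builds GRCm38 and mm10; no label states filters, the counting mode or the strand setting, so reads of overlapping and antisense genes, and of close paralogs and pseudogenes, may have been split in ways that cannot be checked.

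The deposited gene counts are whole numbers of reads per Ensembl gene and, in another file, per RefSeq gene symbol, with a column per library and no normalization. The deposited FPKM values are fragments scaled by gene length and library depth by the authors, for 48795 Ensembl genes; their normalizing depth tracked the library totals (correlation 1 over 8066 genes, with an SD of their ratio of 0.096%). The Ensembl count table as given ended inside a line, which was left out, so 19563 genes were used; genes past that point, Xist and Slc17a7 among them, hold 11.5% of the mean FPKM and were not analysed here in the Ensembl counts. Xist was read from the RefSeq counts (24060 genes), which hold 0 mitochondrially encoded genes. Among the Ensembl genes, 23 symbols had turned into dates, so symbols were taken by Ensembl identifier from the reference gene names (19514 of 19563 matched). Coordinates are from GENCODE vM21, on GRCm38. A deposited RefSeq FPKM table was not used, since the counts of the same genes were.

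Sex was taken from the labels. The label used for the line is tagged as a batch (Arpp19 group and so on). It was read as the line because the design text gives 8 mice per line. Line and batch thus cannot be told apart in any comparison. Columns were matched to libraries by the name in each library's description. Counts were tested as deposited with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling, filterByExpr by line and sex), which kept 14283 genes, in R 4.3.3 with limma 3.58.1 and data.table version 1.17.8. Sex was tested with line as a term; lines were tested by an F-test with sex as a term and each line against the mean of the other 12; the sex effect per line was tested by the interaction of both, and plates with line and sex as terms. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors are the log2 fold change divided by the square root of its F. List scores are the mean over a list's tested members of log2 CPM with a prior count of 2. They were compared by two-sided permutation, 100000 draws, of sex within line or of line within sex, with Benjamini-Hochberg adjustment over 33 lists.

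The comparisons, tests, lists and most alternatives were fixed before the data were examined. The 33 lists cover X genes that escape inactivation, Y genes, sex steroid receptors and enzymes, markers of neurons (pan-neuronal and excitatory, layer 2 to 4, layer 5 and 6, interneurons), of neighbouring regions (striatal, hippocampal, thalamic, hypothalamic and pituitary), of glia and other cells (oligodendrocytes and their precursors, astrocytes, microglia, endothelium, mural cells, meninges and fibroblasts, choroid plexus, ependymal cells, erythroid cells), of states (immediate early, glucocorticoid-responsive, circadian clock, nuclear respiratory chain, mitochondrially encoded, cytosolic ribosomal, heat shock, endoplasmic reticulum chaperones, interferon-stimulated, cholesterol synthesis), genes known to differ between C57BL/6 substrains, and the genes the lines are named after. Lists of cytosolic and mitochondrial aminoacyl-tRNA synthetases were added later.

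Genes were named by a rule. For sex it took the Y and escape lists, then the 10 genes with the largest fold change in each direction among called genes with a mean log2 CPM of at least 1 and the same direction in at least 10 of 13 lines. For lines it took the 15 genes with the smallest p of the F-test, per line the highest and the lowest called gene with a mean log2 CPM of at least 1 and at least 7 of 8 libraries beyond the median of the others, and the gene the line is named after. It further took the 5 smallest p of the interaction, the 3 of the plates, and up to 4 members per list. Genes named outside the rule are said to be so where they appear or, for Dach1, are called genes of that line. A few genes are not reported here by name or value, though counts of called genes and list scores include them.

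Library totals ran from 3.53 to 34.7 M reads. Counts were simulated from the real means and library sizes, as independent libraries with no line differences besides the one tested. Changed genes were drawn only from genes above a minimum mean count, so the shares do not cover genes with few reads. In these counts the sex test found 80% of genes changed 1.1-fold and 100% of those changed 1.25-fold or more. It called 0.078% of unchanged genes (14229 genes). The test of 1 line found 56% at 1.1-fold, 98% at 1.25-fold and 100% above, and called 0.064% of unchanged genes (14216 genes). With 200 simulated lists each, the list test of sex called 3.5% of unchanged lists and 100% of lists raised by 1 SD, and the list test of lines 5.0% and 68.5% with 1 line raised by 1.5 SD.

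Alternatives were DESeq2 1.42.0 as the test, its median-of-ratios size factors, no filter or a stricter filter on low counts (1 CPM in at least 52 libraries), RefSeq counts, limma-trend on log2(FPKM + 0.1) and log2(FPKM + 1), plate 1 only, tissue scores as covariates, no line or no sex term, the replicate number as a block, a test against a 1.2-fold change, females or males only, each line left out, each replicate of every line and sex left out, and list medians. Added after seeing the data were fits without the library with the fewest reads, without 2 or 3 libraries whose sex-linked genes go against the label, without the library with the highest Ttr (for Ttr itself also without the 2 highest), and without the Gsg1l library with the lowest Nnt. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.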

Results

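RNA of the cerebral cortex was sequenced from wild type C57BL/6 mice aged 6 months. The mice came from 13 lines, each carrying the name of a gene in the labels (Arpp19, Dach1, Ece2, Gsg1l, Hrk, Kdm3b, Morf4l1, Pcdh20, Ppp1ca, Rasgef1a, Rgs9, Tbc1d8 and Zswim6), with 4 females and 4 males per line (52 of each sex). Every animal was labelled wild type, so a line here is a group of control animals and not a mutant. The labels tag these groups as batches, so a difference between lines may also be one between batches. Each library came from a separate mouse, so the spread between replicates includes the animals. The labels do not say which mice are related, and the p-values treat all mice as independent. Library totals over the analysed genes ran from 3.53 to 34.7 M reads with a median of 29.5 M. The library with the fewest reads was Kdm3b female replicate 22 and the next lowest held 25.03 M. The medians were 29.3 M in the 52 females and 29.9 M in the 52 males. No pair of libraries agreed within sampling noise: the smallest chi-square per degree of freedom was 2.05 between any libraries and 2.78 between libraries of the same line and sex. The design allowed comparisons of the sexes, of the lines, of the sex difference between lines and of both library plates.

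Sex-linked transcripts separated all but 3 of the libraries as labelled. In 50 libraries labelled female, the Y genes Kdm5d, Uty, Ddx3y and Eif2s3y together held 0 to 5 reads, while Xist, the non-coding RNA that silences the inactive X chromosome, held 3598 to 37059. In 51 libraries labelled male the same Y genes held 4077 to 5832 reads and Xist 0 to 16. The remaining 3 libraries went against their labels. The library labelled Rgs9 female replicate 43 held 4988 Y gene reads and 3 Xist reads, and the library labelled Rasgef1a male replicate 40 held 0 Y gene reads and 32425 Xist reads. The library labelled Rasgef1a female replicate 39 held 0 Y gene reads and 2 Xist reads. All libraries were analysed as labelled, and every directional statement on sex below carries these 3 libraries. The comparisons of the Rgs9 and Rasgef1a lines carry them too.

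**Figure D1:**
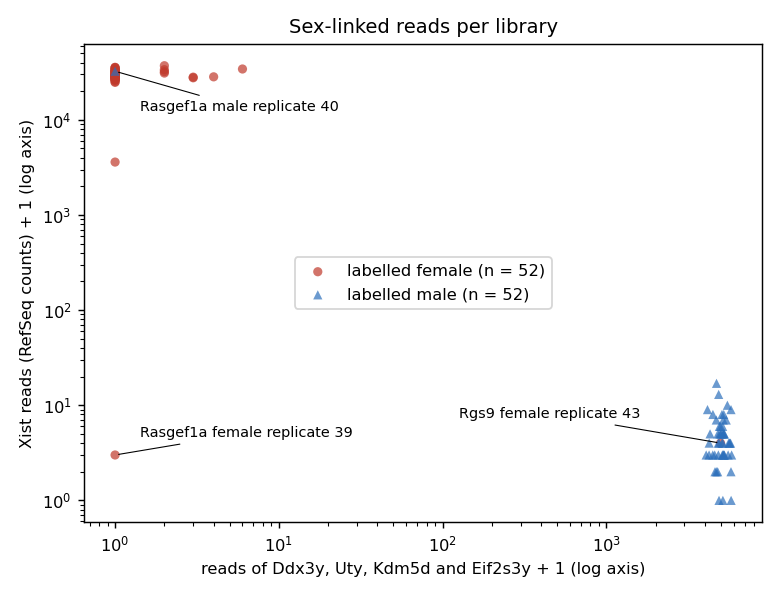
Reads of Xist against the summed reads of Kdm5d, Uty, Ddx3y and Eif2s3y in each library, by sex label. Of the 3 libraries that go against their labels, 1 lies among the libraries labelled male (4988 Y gene reads), 1 among those labelled female (32425 Xist reads) and 1 outside both clusters, with 0 Y gene reads and 2 Xist reads.

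Between the sexes, X genes that escape inactivation were higher in females and Y genes lower. Eif2s3x, a subunit of translation initiation factor eIF2, was at 18.2 ± 1.90 CPM (counts scaled to library size; SD, n = 52) in females and 12.3 ± 1.16 in males, a log2 difference of 0.57 ± 0.03 (standard error). The histone demethylases Kdm6a (0.36 ± 0.03) and Kdm5c (0.30 ± 0.02), the RNA helicase Ddx3x (0.29 ± 0.02) and Pbdc1 (0.29 ± 0.02) followed, each higher in females in all 13 lines. Utp14a was 0.07 ± 0.02 higher, with an adjusted p of 0.0306 that became 0.0661 in the authors' RefSeq counts and reached 0.107 without the line Kdm3b (the call ended without any 1 of 6 lines), and Mid1 missed the threshold at 0.21 ± 0.09 (adjusted p = 0.101), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 7 tested members of the escape list, 6 passed over all genes and 7 when adjusted over the list alone. All 4 tested Y genes were lower in females, also when adjusted over the list alone: Kdm5d by -5.78 ± 0.26, Uty by -5.75 ± 0.24, Ddx3y by -5.94 ± 0.27 and Eif2s3y by -5.76 ± 0.26. These Y fold changes rested on the library labelled Rgs9 female replicate 43: without the 3 libraries that go against their labels Kdm5d came to -12.34 and Ddx3y to -13.42, fitted values that depend on the prior count and are no bounds. Reads of the X and Y copies of Ddx3, Kdm5, Eif2s3 and their kin resemble each other, so their split rests on the authors' counting.

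Many autosomal genes differed by sex, most of them by little. Of 14283 tested genes, 692 were higher in females and 649 higher in males, and outside the sex chromosomes their median log2 differences were 0.07 and -0.06. Only 60 of the female-higher and 31 of the male-higher genes were over 1.2-fold apart, and 656 and 612 had the same sign in at least 10 of the 13 lines. Of the female-higher genes 34 lay on the X, which held 491 of the tested genes (two-sided Fisher's exact test across genes, which are not independent replicates, p = 0.041); of the male-higher genes 19 did (p = 0.58), and 5 lay on the Y. Stra6, the cell-surface receptor for retinol-binding protein (chromosome 9, 58063788 to 58153996, GRCm38), stood at 7.29 ± 2.10 CPM in females and 5.37 ± 1.65 in males (0.44 ± 0.08). Aldh1a1, a retinaldehyde dehydrogenase, was 0.25 ± 0.03 higher in females, in all 13 lines. Also higher in females were Tnfrsf8 (0.32), Stk32b (0.30), the clustered protocadherins Pcdhb6 (0.30) and Pcdhb2 (0.27), Abi3bp (0.29), F2rl2 (0.26), Greb1 (0.25), an oestrogen-induced gene, and Gkn3 (0.25). The protocadherin genes are close copies of one another, and their split of reads is uncertain.

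Several activity-regulated transcription factors were higher in males. Junb was at 72.3 ± 29 CPM in females and 89.1 ± 26.3 in males (-0.32 ± 0.09), Npas4 at 36.6 ± 13.8 and 45 ± 15.8 (-0.31 ± 0.08), Fos at -0.30 ± 0.10 and Nr4a1 at -0.24 ± 0.08. Ptgs2, the inducible cyclooxygenase, was at -0.21 ± 0.07 and the neuropeptide gene Cartpt at -0.27 ± 0.04, the latter lower in females in all 13 lines. Ccbe1 (-0.25), Col5a3 (-0.21), Sntg2 (-0.20) and Lsp1 (-0.20) completed the 10 genes with the largest differences under the naming rule, which asks for a minimum level and the same direction in at least 10 lines. Called genes that the rule leaves out had larger differences than some of these, among them Ttr and Trh (-0.37 ± 0.12), as had the Y genes. With scores of striatal, oligodendrocyte, choroid plexus and erythroid genes as covariates, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment no longer called Fos (-0.28, adjusted p = 0.0694), Nr4a1 (-0.23, 0.055), Ptgs2 (-0.14, 0.13) or Gkn3 (0.22, 0.0842). Of these, Ptgs2 moved most from its value without covariates. The same test lost these calls when single lines were left out, with an adjusted p of up to 0.104 for Fos, 0.0832 for Nr4a1, 0.082 for Ptgs2 and 0.112 for Gkn3, and lost Fos (0.0538) without the 3 libraries that go against their labels, where 635 genes were higher in females and 698 in males. Within plate 1 alone, 601 genes were higher in females and 617 in males; plate 2 held 8 libraries of several lines, too few for the comparison.

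Of 33 gene lists fixed before the data were examined, 12 differed between the sexes by their mean score. Oligodendrocyte precursor genes averaged 0.08 higher in females (log2 CPM), in all 13 lines (permutation of sex within line, adjusted p = 0.00011, from the smallest p that 100000 permutations can give, 1e-05). Of 7 tested members 3 were higher in females, also when adjusted over the list alone: Gpr17 (0.19 ± 0.03), Vcan (0.11 ± 0.02) and Cacng4 (0.09 ± 0.02). The escape genes averaged 0.30 higher and the Y genes -8.77, both at the same smallest p. Sex steroid receptors and enzymes were 0.09 higher in females in 12 of 13 lines (permutation, adjusted p = 0.000412), led by the oestrogen receptor Esr1 (0.25 ± 0.06) and Greb1, 2 of 7 members by either adjustment, the second being adjusted over the list alone. Endothelial genes were 0.05 higher (permutation, adjusted p = 0.0256; Abcb1a 0.07 ± 0.02; 1 of 11 members, 3 adjusted over the list alone), and interferon-stimulated genes 0.10 higher (permutation, adjusted p = 0.043; Oas2 0.33 ± 0.09 and Ifit1 0.19 ± 0.06; 2 of 11 members, 4 adjusted over the list alone). Thalamic markers were 0.04 higher (permutation, adjusted p = 0.0395), with Ramp3 at 0.09 ± 0.03 and Synpo2 at 0.09 ± 0.04 short of the gene threshold, while the median of the members gave -0.001.

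Among the lists lower in females, immediate early genes came first by size after the Y genes, at -0.21 (permutation, adjusted p = 0.0256). Of their 17 members 4 passed, and 7 adjusted over the list alone. Cholesterol synthesis genes lay at -0.07 (permutation, adjusted p = 0.00962), with Lss at -0.13 ± 0.03 and Fdps at -0.09 ± 0.02; 6 of 19 members passed and 12 adjusted over the list alone. Cytosolic ribosomal protein genes lay at -0.03 (permutation, adjusted p = 0.0188), with Rps15 and Rpl3 both at -0.07 ± 0.02; 8 of 30 passed and 14 adjusted over the list alone, and processed pseudogenes of these genes can take some of their reads. Interneuron genes were at -0.03 (permutation, adjusted p = 0.00224), with the serotonin receptor Htr3a at -0.17 ± 0.03 lower in females in all 13 lines; 1 of 11 members passed and 2 adjusted over the list alone. Mural cell genes were at -0.05 (permutation, adjusted p = 0.0395), with Kcnj8 and Myh11 both at -0.11 ± 0.04; 2 of 8 passed and 3 adjusted over the list alone. Scored by the median of the members, the interneuron, endothelial, interferon and sex steroid lists missed the threshold, and without the 3 libraries that go against their labels so did the mural list (permutation, adjusted p = 0.0754). The interferon list also missed it under the stricter filter on low counts (0.0723) and on log2(FPKM + 0.1) values (0.0583), the thalamic list on the latter (0.0587) and the mural list on log2(FPKM + 1) values (0.0545). Without Gsg1l female replicate 14 the mural (0.052), interferon (0.0548) and thalamic (0.0548) lists missed it by the same permutation test, and so did the mural list within plate 1 (0.0871).

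**Figure D2:**
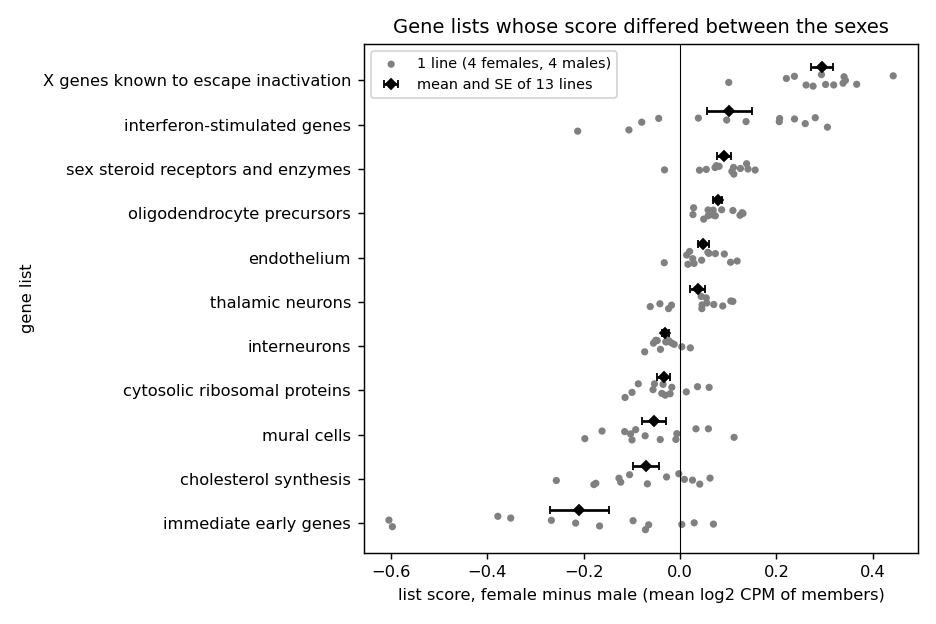
Difference of gene list scores between females and males (mean log2 CPM of the members), 1 point per line, with the mean and standard error of the 13 lines for each list; the Y list lies off the scale and is left out. Oligodendrocyte precursor and escape genes lie above 0 in all 13 lines, and immediate early genes lie above 0 in 3 of them.

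The other 21 lists did not pass between the sexes, with adjusted permutation p from 0.0874 to 0.994. Neuronal lists differed by -0.004 (pan-neuronal and excitatory), 0.01 (layer 2 to 4), -0.06 (layer 5 and 6), -0.005 (striatal projection neurons), 0.08 (hippocampal) and -0.04 (hypothalamic and pituitary peptides). Glial and border lists differed by 0.06 (oligodendrocytes), 0.03 (astrocytes), 0.0 (microglia), 0.11 (meninges and fibroblasts), -0.09 (choroid plexus), -0.002 (ependymal cells) and -0.08 (erythroid). State lists differed by -0.02 (glucocorticoid-responsive), -0.02 (circadian clock), 0.002 (nuclear respiratory chain), 0.04 (mitochondrially encoded), 0.02 (heat shock) and 0.05 (endoplasmic reticulum chaperones), and the substrain list and the genes the lines are named after by 0.02 each. The hippocampal list passed within plate 1 (0.11, permutation, adjusted p = 0.0168), without a filter on low counts (0.037) and on log2(FPKM + 1) values (0.0466). Scored by medians the layer 2 to 4, hippocampal, astrocyte and mitochondrially encoded lists passed. Single members still stood apart: the microglial Fcrls was 0.21 ± 0.03 higher in females and Ctss was at -0.08 ± 0.02, each the same way in all 13 lines, the striatal Ppp1r1b was at -0.13 ± 0.02 and the astrocytic S100b at 0.10 ± 0.02. The choroid plexus gene Ttr was at -3.53 ± 0.52 between the sexes. This rested on Rasgef1a male replicate 37 (275 CPM) and Arpp19 male replicate 1 (19.3 CPM), as every other library held 1.97 CPM or less. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Ttr was at -1.08 ± 0.32 without the first (adjusted p = 0.0198) and at -0.24 ± 0.20 without both (0.499).

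Between the lines, Tbc1d8 and Gsg1l mice stood apart from the rest. Nnt, the mitochondrial proton-pumping transhydrogenase (chromosome 13, 119335448 to 119408997, GRCm38), was at 32.7 ± 1.35 CPM in Tbc1d8 (SD, n = 8) and 31.1 ± 3.28 in Gsg1l, while the means of the other 11 lines ran from 21.3 (Kdm3b) to 22.8 (Hrk). The log2 differences from the mean of the other 12 lines were 0.53 and 0.46. Gabra2, a GABA-A receptor subunit (chromosome 5, 70957597 to 71095849), was 0.76 higher in Tbc1d8 (90.9 ± 7.0 CPM) and 0.58 higher in Gsg1l (81.2 ± 15.8), with Dach1 next at 68.4 ± 13.5 and the other 10 lines between 48.6 and 52.6. Several of the genes with the smallest p or the largest folds were lower in both lines: asparagine synthetase Asns by -0.40 in Tbc1d8 (79.1 ± 5.31 CPM) and -0.29 in Gsg1l (85.3 ± 11.4), and the stress-response transcription factor Atf4 by -0.44 and -0.33. So were the cationic amino acid transporters Slc7a1 by -0.33 and -0.29 and Slc7a3 by -0.93 and -0.63, the folate enzyme Mthfd2 by -0.80 and -0.78, and the asparaginyl-tRNA synthetase Nars by -0.27 and -0.21. In Tbc1d8, Adar (-0.28), Tspyl4 (-0.26), Nudt3 (-0.31), Fbxw11 (-0.22), Mfn2 (-0.21) and Mybpc1 (-0.65) were also lower and R3hdm4 (0.25) and Jpt1 (0.29) higher. In Gsg1l the log2 differences of these genes had the same signs, with Adar at -0.21, Tspyl4 at -0.22, Nudt3 at -0.23, Fbxw11 at -0.21, Mfn2 at -0.16, Mybpc1 at -0.47, R3hdm4 at 0.21 and Jpt1 at 0.29. Dach1 means lay next to those of both lines for several genes with a wide spread, among them Atf4 (135 ± 23.9 CPM), Nudt3 (291 ± 31.6) and Adar (282 ± 22.8). The lowest Dach1 library of a gene reached the range of Tbc1d8 for Asns (6.386 log2 CPM, highest Tbc1d8 library 6.389) and Atf4 (6.707, highest Tbc1d8 library 6.85). Others where it did included Nudt3 (7.969, highest Tbc1d8 library 8.036), Nars (7.664 and 7.711) and Fbxw11 (7.158 and 7.243). The highest Dach1 library reached that range for Gabra2 (6.473, lowest Tbc1d8 library 6.285). For Mybpc1 the lowest did not reach it (3.036, highest Tbc1d8 library 2.979). Nnt in Dach1, at 21.4 ± 1.33 CPM, lay among the means of the other lines. In Gsg1l the called gene highest by fold under the naming rule was Tnfrsf8 (0.63 ± 0.12). In males only, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment lost it (0.54, adjusted p = 0.0775).

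In all, 1452 genes differed between lines by edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment, with Nnt first (F = 41, adjusted p = 2.08e-28). Against the mean of the other 12 lines, 855 genes were higher and 969 lower in Tbc1d8, and 771 higher and 826 lower in Gsg1l. Within plate 1 the counts were 1029 genes in Tbc1d8 and 1499 in Gsg1l, and with tissue scores as covariates 1141 and 1161, and 822 between all lines. Gsg1l female replicate 14 did not share the line's values: its Nnt was 4.57 log2 CPM against 4.94 or more in the other 7, and without it 1981 genes were apart in Gsg1l.

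**Figure D3:**
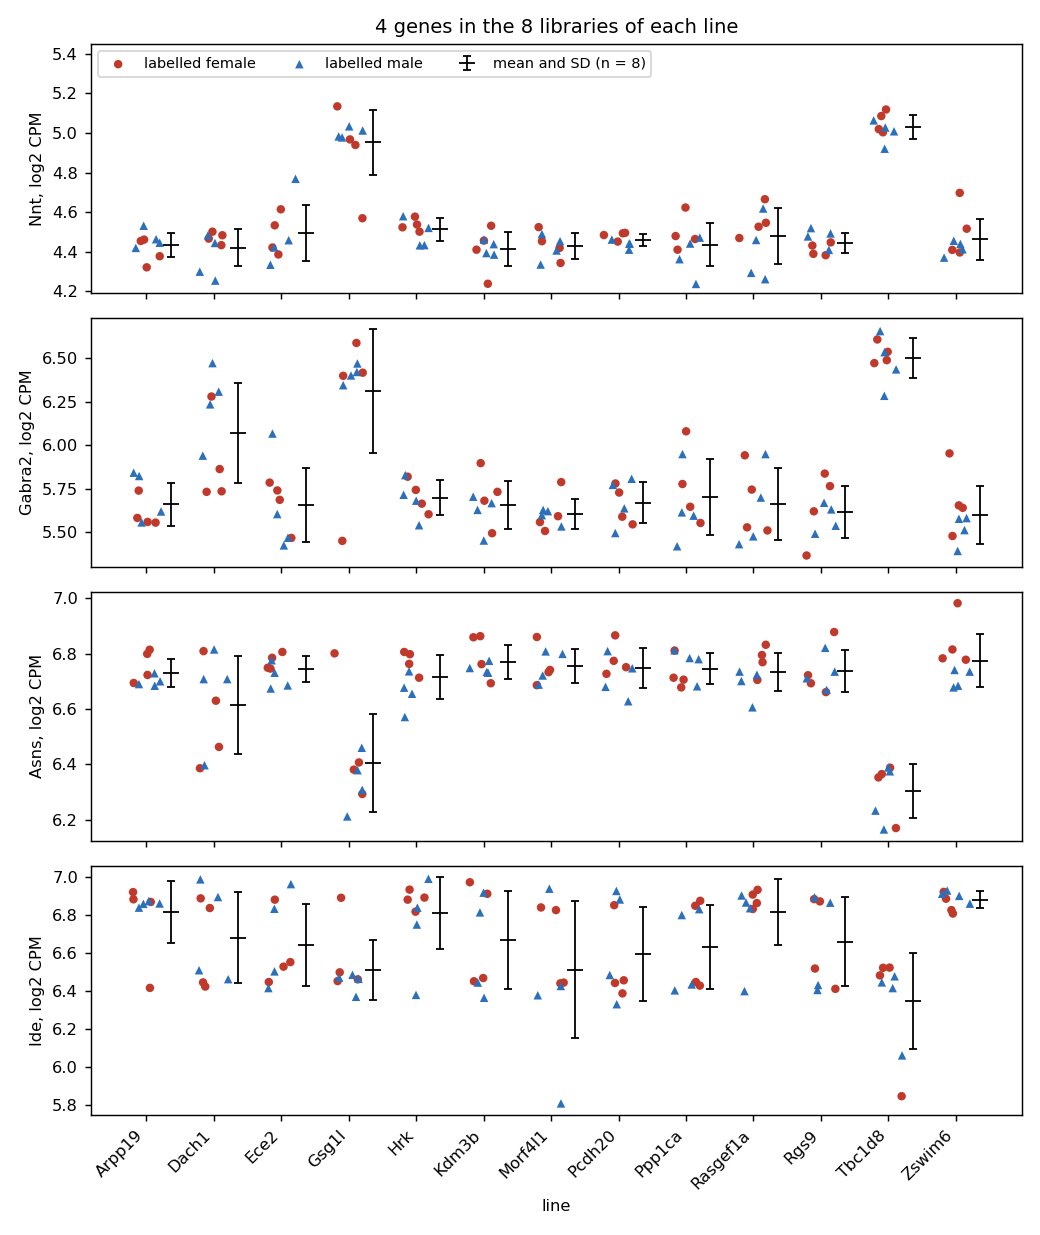
Nnt, Gabra2, Asns and Ide in each library by line (log2 CPM), with the mean and SD of the 8 mice per line. By mean, Gsg1l and Tbc1d8 lie above the other lines for Nnt and Gabra2 and lowest for Asns (85.3 and 79.1 CPM, Dach1 next at 98.6), while Ide varies between libraries inside several lines.

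Of 33 lists, 2 differed between lines. Genes known to differ between C57BL/6 substrains (4 tested, among them Nnt, Gabra2 and Ide) had the largest F, 15.33 (permutation of line within sex, adjusted p = 0.00033, from the smallest p that 100000 permutations can give), with Tbc1d8 furthest from the rest at 0.26; 3 of the 4 passed the line test and 4 adjusted over the list alone. Ide, the insulin-degrading enzyme, went the other way in Tbc1d8 (-0.34 ± 0.08). Sex steroid receptors and enzymes gave F = 3.02 (permutation, adjusted p = 0.0279), with Dach1 furthest at 0.12 and 1 member, Greb1, past the line test, also when adjusted over the list alone; that call was lost in the RefSeq counts (permutation, adjusted p = 0.162) without a filter on low counts (0.0563) and on log2(FPKM + 1) values (0.306). The other 31 lists had adjusted permutation p from 0.0751 (thalamic neurons) to 0.833 (layer 5 and 6 neurons). Single members of these passed the gene test, among them the respiratory chain gene Cox8a (0.19 ± 0.03 in Gsg1l), the interneuron transcription factor Dlx1 (0.20 ± 0.04 in Gsg1l), the clock genes Hlf (-0.18 ± 0.03 in Tbc1d8) and Cry1 (-0.32 ± 0.07 in Tbc1d8), and Npas4 (0.62 ± 0.14 in Tbc1d8). Some alternatives of the permutation test gained calls between lines. The thalamic list passed on log2(FPKM + 0.1) values (adjusted p = 0.0208) and log2(FPKM + 1) values (0.00825). Without the 3 libraries that go against their labels, the thalamic and the pan-neuronal lists passed (0.0492 each). Scored by medians, the striatal, glucocorticoid-responsive and endoplasmic reticulum chaperone lists passed.

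Dach1 mice differed from the rest in 18 genes, 7 higher and 11 lower, most of them on chromosomes 12 and 13. On chromosome 12 these included Greb1 (0.92 ± 0.10), Odc1, the first enzyme of polyamine synthesis (-0.32 ± 0.04), Kidins220 (-0.08), Adi1 of the methionine salvage pathway (0.47 ± 0.04), Pxdn (-0.31), the phosphatase Acp1 (-0.55 ± 0.05) and Prkar2b (0.11), between 16670615 and 32061296 (GRCm38). On chromosome 13 they were Mtrr, methionine synthase reductase (-0.60 ± 0.08), Fastkd3 (-0.47), 1700001L19Rik (-0.54), Adcy2, an adenylate cyclase (-0.36 ± 0.04), and Brd9 (0.10), between 68560780 and 73960895. The others were Rec8 (-1.54 ± 0.20), Cndp2, Gm9493, Gabra2 (0.31 ± 0.07) and Cox7b2 (1.2 ± 0.23); Gm9493 is a processed pseudogene whose reads can come from its parent gene. Acp1 was at 14.6 to 16 CPM in 6 Dach1 libraries and at 25.4 and 25.5 in Dach1 female replicate 5 and male replicate 7, inside the range of the other lines (23.1 to 29.5). These 2 libraries were the Dach1 libraries of plate 2, and Adi1 and Greb1 split the line the same way, with Adi1 at 17.8 and 18.2 CPM in them and at 27.2 to 33 in the other 6.

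**Figure D4:**
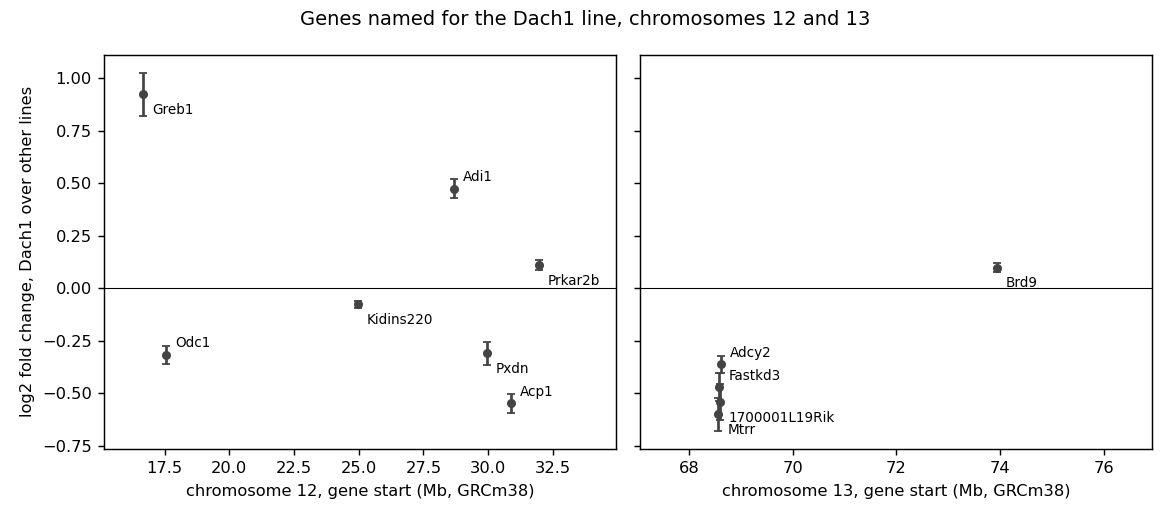
Log2 fold change of Dach1 against the other 12 lines, with standard error, by gene start on chromosomes 12 and 13 (GRCm38). The genes shown, those named for the line on these chromosomes, lie in stretches that begin at Greb1 (16670615) on chromosome 12 and at Mtrr (68560780) on chromosome 13.

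Rasgef1a had 16 genes apart, led by markers of the choroid plexus, and 1 library carried them. Ttr, the thyroid hormone carrier transthyretin, was 6.08 ± 0.37 higher by fit, but it reached 275 CPM in Rasgef1a male replicate 37 and 0.206 to 1.97 in the other 7; without that library the difference was 0.64 (adjusted p = 0.986 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and the gene that stood apart was Eya3 (0.22 ± 0.04), named after its value was seen. Without the 3 libraries that go against their labels 9 genes stood apart. Plin4, a lipid droplet protein, was 1.19 ± 0.27 higher with 26.5 CPM in the same library and 1.68 to 4.95 in the others, and 0.35 without it. Clic6 (1.99 ± 0.34) and Sostdc1 (1.19 ± 0.26), also of the choroid plexus list, came from the same comparison.

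The remaining lines gave 0 to 3 genes. Pcdh20 had Stxbp4 (0.26 ± 0.04), Cplx2 (-0.24 ± 0.05) and Adamts17 (0.31 ± 0.07). Arpp19 had Dock4 (-0.22 ± 0.04; 157 ± 27.1 CPM against 183 ± 11.6), Ece2 the zinc finger gene Zfp879 (-0.41 ± 0.08), Morf4l1 Mybpc1 (0.28 ± 0.06) and Rgs9 the transcription factor Rfx4 (0.25 ± 0.05), for which Rgs9 female replicate 44 and male replicate 44 stood at 24.8 and 23 CPM and the other 6 at 14.6 to 18.6. Kdm3b had Lcn2 (2.43), a single-library value: 2.47 CPM in Kdm3b male replicate 24 and 0.0632 or less in the other 7, and DESeq2 called 0 genes in Kdm3b. Cplx2, Adamts17 and Lcn2 were named because a count of 3 or fewer was reported, after their values were seen. For Mybpc1 the mean of the other 12 lines includes Gsg1l (7.91 CPM) and Tbc1d8 (7), where it was low. Morf4l1 stood at 12.7 ± 0.85 CPM, with Ppp1ca next at 11.9 ± 0.80. Mybpc1 in Morf4l1 and Rfx4 in Rgs9 were lost within plate 1 (adjusted p = 0.0988 and 0.926 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With 4 mice per line, the same test in females only lost Zfp879 in Ece2 (-0.38, adjusted p = 1), Stxbp4 in Pcdh20 (0.22, 1), Dock4 in Arpp19 (-0.15, 0.995), Mybpc1 in Morf4l1 (0.29, 0.506) and Rfx4 in Rgs9 (0.32, 0.254). In males only it lost Zfp879 (-0.45, 0.607), Stxbp4 (0.29, 1), Mybpc1 (0.26, 0.191) and Rfx4 (0.19, 0.885). By the same edgeR test 0 genes passed in Hrk, Ppp1ca and Zswim6, with 696, 630 and 790 at an unadjusted p under 0.05 and 1, 0 and 0 by DESeq2.

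The gene each line is named after did not mark its line. The largest difference was that of Gsg1l in Gsg1l mice (117 ± 6.58 CPM, n = 8, against 111 ± 8.06, n = 96; 0.08 ± 0.04), with an adjusted p over the 13 tests of 0.343 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ece2 was at -0.05 ± 0.05 in Ece2 mice, Hrk at -0.05 ± 0.09 in Hrk mice, Dach1 at 0.04 ± 0.07 in Dach1 mice and Tbc1d8 at -0.01 ± 0.04 in Tbc1d8 mice, and Morf4l1 at -0.002 ± 0.03 had the highest adjusted p, 0.953.

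The sex difference itself differed between lines for 3 genes, all on the Y: Eif2s3y (adjusted p = 0.000298), Kdm5d (0.000623) and Ddx3y (0.00286), by edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment. Uty (0.0601) and Cplx2 (0.183) came next. Without the library labelled Rgs9 female replicate 43 and the library labelled Rasgef1a male replicate 40, 0 genes passed that edgeR test (587 at an unadjusted p under 0.05), as also without all 3 libraries that go against their labels (594). With all libraries edgeR had 590 genes at an unadjusted p under 0.05. DESeq2 called 2 genes, Cplx2 (adjusted p = 0.0303) and Ttr, and not Eif2s3y (0.0819) or Kdm5d (0.13). Limma-trend on FPKM values called Cplx2 alone (0.0251 with 0.1 added), with an adjusted p of 0.999 for Eif2s3y, Kdm5d and Ddx3y.

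Plate 2, with 8 libraries of 6 lines, differed from plate 1, with 96, in 53 genes, 31 higher and 22 lower. Dpysl2, a microtubule-associated protein of growing axons, was at 228 ± 12.9 CPM on plate 2 and 266 ± 15.7 on plate 1 (-0.23 ± 0.03, adjusted p = 2.65e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The transcription factor Nfia (-0.25 ± 0.04) and Apbb2, a binding partner of the amyloid precursor protein (-0.16 ± 0.03), were next. DESeq2 called 123 genes, and with tissue scores as covariates edgeR called 5.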

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

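The tests weighed here were chosen after the results were seen, except those of library depth and of the mitochondrial synthetases; the splits of the samples were planned, but their predictions were written afterwards. No sample was removed from the values in the report.

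The sex-linked genes of 3 libraries went against the label, with 32425 Xist reads in the library labelled Rasgef1a male replicate 40. RNA of a male and a female mixed in 1 library is argued against, because the smaller of the Xist and Y gene read counts reached at most 3 in these libraries. A wrong label may account for that library and the library labelled Rgs9 female replicate 43, since all 5 X escape genes checked lay nearer the mean of the opposite sex in both. Whether their line labels are right was not tested. In the library labelled Rasgef1a female replicate 39, with 2 Xist and 0 Y gene reads, 4 of the 5 lay below the lowest of the 50 females whose reads go with the label (Eif2s3x at 3.44 log2 CPM, lowest female 3.96), so a single X chromosome is a candidate explanation; a male that lost Y reads was not tested. The sex difference of Eif2s3y, Kdm5d and Ddx3y differed between lines by an interaction test (adjusted p = 0.000298, 0.000623 and 0.00286 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment); without those libraries edgeR called 0 genes, with 594 at an unadjusted p under 0.05, and DESeq2 was run with all libraries only (2 genes, Cplx2 and Ttr).

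In Gsg1l and Tbc1d8 over 1000 genes stood apart. Plate is argued against, since within plate 1 the line with fewer genes apart still had 1029. Tissue makeup, as read by striatal, oligodendrocyte, choroid plexus and erythroid scores, does not account for all of the pattern. With these scores in the model 1141 of 1824 genes were left in Tbc1d8 by count, and 1161 of 1597 in Gsg1l. Scores of other cell types were not entered, so makeup in general stays open. Depth is argued against, since the mean total of Tbc1d8, 29.3 M reads, lay inside the range of the other lines. A different genetic background of these mice may account for the pattern: the substrain list had the largest F of all lists, 15.33, with Tbc1d8 and Gsg1l furthest out, while the labels give C57BL/6 for every mouse. Cytosolic aminoacyl-tRNA synthetases were lower in Tbc1d8 (-0.117, 13 of 20 members, permutation p = 1e-05, the smallest the permutations can give). The mitochondrial ones moved by 0.008 (permutation p = 0.569), so a change shared by every kind of synthetase is argued against. Line cannot be told apart from the labels' batch. Other differences between the lines stay open and were not tested.

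Of the 18 genes apart in Dach1, 29 pairs lay within 10 Mb of each other, against a median of 1 and at most 11 in 10000 random sets (permutation p = 1e-04, the smallest the sets can give). Tissue makeup, as far as striatal, oligodendrocyte, choroid plexus and erythroid scores read it, is argued against, since 20 genes stood apart with these scores in the model. Neighbouring genes that stand apart, some higher and some lower, may point to a stretch of other genetic origin in these mice. The deposited counts alone do not test this. The gene Dach1 itself lies on chromosome 14, outside the stretches on chromosomes 12 and 13. The same count was 0 in Rasgef1a (p = 1), and in Gsg1l and Tbc1d8 it was as in random sets (p = 0.438 and 0.547).

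The splits regroup single mice, whereas the 18 pairs of a line whose names share a middle number all carry the same sex label. Chance would thus be excluded below only if mice count as independent. The residuals of these pairs correlated at -0.035, against -0.322 with permuted numbers (permutation p = 1e-04), which goes against that. Were mice independent, chance would be excluded for the sex counts. Of 100 splits 1, the real one, gave as many genes higher in females (692, highest other 3). For genes higher in males 1 did (649, highest other 1). On the same condition it would be excluded for lines (1452, highest other 10, 1 of 100), for Gsg1l (1597, highest other 16, 1 of 100) and for Tbc1d8 (1824, highest other 183, 1 of 100). By the share of splits Dach1 (18, highest other 149, 3 of 100) and plates (53, highest other 114, 2 of 100) also passed the limit set for excluding chance. Single splits called more genes, and the limit was not adjusted for the number of counts judged by it. The plate splits ignored line and sex. By these splits alone, chance thus stays open for Dach1 and for plates. The splits do not use where the Dach1 genes lie. For Rasgef1a (16, highest other 1085; 3 of 100) the splits leave open where a single library falls by chance, since without male replicate 37 the line had 1 gene apart. It cannot be excluded for the interaction (3, highest other 31; 7 of 100), Arpp19 (1, highest other 249; 28 of 100), Ece2 (1, highest other 388; 28 of 100), Kdm3b (1, highest other 76; 24 of 100), Morf4l1 (1, highest other 1794; 22 of 100), Pcdh20 (3, highest other 107; 11 of 100) or Rgs9 (1, highest other 92; 20 of 100). For Hrk, Ppp1ca and Zswim6 the splits decide nothing: edgeR called 0 genes (696, 630 and 790 at an unadjusted p under 0.05; 1, 0 and 0 by DESeq2), so each of the 100 splits gave as many by construction, the highest others being 16, 379 and 28. The line splits moved every mouse within its sex label, so Gsg1l and Tbc1d8 mice, which share many differences, entered the regrouped lines. Whether this made the splits that called several times the real count, as for Morf4l1, Rasgef1a, Dach1 and Arpp19, was not tested. These splits are thus no clean measure of chance, and they cannot decide on lines with few genes apart.

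Within lines, 33 of 455 tests of the highest or lowest library against its neighbours passed Dixon's critical value (7.25%, where chance gives about 1 in 20), in 22 libraries. Kdm3b female replicate 22 had 3.53 M reads and 14136 detected genes, and stood low for ependymal (-0.93), interferon-stimulated (0.13) and cholesterol synthesis genes (5.29). Totals were high in Hrk male replicate 20 (31.89 M) and Rgs9 female replicate 42 (32.98 M), and detected genes in Gsg1l female replicate 15 (15750). Scores in log2 CPM stood apart for the choroid plexus in Arpp19 male replicate 1 (0.29) and Rasgef1a male replicate 37 (2.92, with glucocorticoid-responsive genes at 5.30). The substrain list stood apart in Arpp19 female replicate 4 (5.91) and Gsg1l female replicate 14 (6.08), and meningeal genes in Ece2 male replicate 12 (1.37) and the library labelled Rasgef1a female replicate 39 (1.78). Chaperones of the endoplasmic reticulum did in Gsg1l male replicate 14 (6.26, with heat shock genes at 6.21), Kdm3b female replicate 21 (5.95) and Ppp1ca female replicate 36 (6.26, with cholesterol synthesis at 4.97). Nuclear respiratory chain genes did in Gsg1l male replicate 13 (6.21), mitochondrially encoded genes in Pcdh20 female replicate 30 (6.92), and layer 2 to 4 (6.87), layer 5 and 6 (3.46) and immediate early genes (6.02) in Pcdh20 male replicate 30. Oligodendrocyte genes did in Morf4l1 male replicate 26 (6.06) and Zswim6 female replicate 50 (5.86, precursors 4.35), glucocorticoid-responsive genes in Rgs9 male replicate 44 (5.01) and Zswim6 female replicate 52 (4.78, interferon-stimulated 1.80), ependymal genes in Tbc1d8 female replicate 48 (-0.46), and interferon-stimulated genes in Tbc1d8 female replicate 46 (1.34).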

How the results depend on the processing

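Fits that left out doubted libraries were chosen after seeing the data; all other alternatives were planned. Of the counts of called genes and lists, 276 values under an alternative stayed within 1.5 times the reported count and 80 did not. Of the list scores 852 kept their call, 17 gained it, 17 lost it and 1 turned its sign, and of the named genes 1589, 9, 117 and 1; a change of sign where neither value passed counted as kept. At these depths and group sizes, simulation found 56% of genes changed 1.1-fold in 1 line, among genes above a minimum mean count. It did not vary depth by itself. The lowest depth was 3.53 M reads in Kdm3b female replicate 22. Where a cause is not named below, the cause was not tested.

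A test against a 1.2-fold change left 5 genes higher in females and 8 in males, as its construction asks for larger changes. Leaving out 1 line gave 450 (without Hrk) to 692 genes higher in females and 484 (without Tbc1d8) to 777 (without Dach1) higher in males. Female and male counts otherwise stayed within 1.5 times, and the lists that differed between sexes numbered 9 to 13. With the replicate number as a block in place of the line, 741 and 657 genes and 12 lists passed; the numbers share only a number, since same-numbered pairs correlated at 0.061 on average (-0.47 to 0.584, 22 of 52 over 0.1) and 16 libraries correlated best with their own number, where chance gives 13.

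With fewer samples, females only gave 137 genes between lines, 435 in Tbc1d8, 141 in Gsg1l, 11 in Dach1, 1 in Pcdh20 and 0 in Arpp19, Ece2, Kdm3b, Morf4l1, Rasgef1a and Rgs9, and Ttr in Rasgef1a turned to -0.39, as the library that carried it is male. Males only gave 454 between lines, 640 in Tbc1d8, 918 in Gsg1l, 10 in Dach1, 5 in Kdm3b and Rasgef1a and 0 in Pcdh20 and Rgs9. Both fits held 4 mice per line, so fewer samples alone do not account for 141 against 918 genes in Gsg1l. The females included Gsg1l female replicate 14, which did not share the line's values, but its part in this was not tested. Plate 1 only gave 1029 in Tbc1d8, 1 in Hrk and 0 in Morf4l1 and Rgs9. Leaving out 1 replicate of every line and sex gave 1 to 4 genes of differing sex effect.

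Tissue covariates gave 822 genes between lines, 5 between plates, 1141 in Tbc1d8, 41 in Morf4l1, 2 in Arpp19, 1 in Hrk and Rasgef1a and 0 in Rgs9. DESeq2 gave 123 between plates, 9 in Morf4l1, 3 in Rgs9, 2 in Ece2, 1 in Hrk and 0 in Kdm3b. RefSeq counts gave 5 genes of differing sex effect, 6 in Morf4l1, 3 in Rgs9 and 1 list between lines. The FPKM values with 0.1 added gave 42 in Kdm3b, with 1 added 29; both gave 1 gene of differing sex effect, 1 in Rasgef1a and 0 in Morf4l1 and Rgs9. No filter gave 2 in Ppp1ca and Rgs9, 0 in Morf4l1 and 1 list between lines; the stricter filter, testing fewer genes, gave 8 in Rasgef1a and 0 in Kdm3b. Medians of members gave 5 lists between lines and turned the thalamic sex difference to -0.001.

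Without the 2 libraries whose Y genes go against the label, 0 genes had a differing sex effect, with 0 in Morf4l1, 1 in Ppp1ca, 2 in Rgs9 and 4 lists between lines; without all 3 libraries the same values held, and 9 genes stood apart in Rasgef1a. Without the library with the highest Ttr, 1 gene stood apart in Rasgef1a and 2 in Arpp19 and Hrk. Without the library with the fewest reads there were 0 in Morf4l1, and without the Gsg1l library with the lowest Nnt 1 in Ppp1ca.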

Other observations

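The test of libraries whose names share a number was chosen before its result was seen; the other comparisons here were chosen after. Cplx2, which encodes the synaptic release regulator complexin, was low in 3 of the 8 Pcdh20 libraries: 654 CPM in Pcdh20 female replicate 31, 722 in female replicate 30 and 725 in female replicate 32. The other 5 Pcdh20 libraries lay between 1200 and 1250 CPM, and the 96 libraries of the other lines between 1080 and 1380. Its sex difference across lines missed the threshold in edgeR (adjusted p = 0.183) and passed in DESeq2 (0.0303) and in limma-trend on FPKM values (0.0251 with 0.1 added), both with Benjamini-Hochberg adjustment. Over all its alternatives the adjusted p ran from 6.98e-10, without replicate 1 of every line and sex, to 1.

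Ide, the insulin-degrading enzyme, fell into separate ranges across the libraries of all 13 lines, with 3 at 5.81 to 6.06, 46 at 6.33 to 6.55 and 55 at 6.75 to 6.99 log2 CPM. The Tbc1d8 libraries lay in 2 of these ranges, from 57.5 to 92 CPM.

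Set against the other 11 lines, Gsg1l and Tbc1d8 shared 535 of 1024 and 1059 higher genes (75.9 in independent lists). They shared 666 of 1059 and 1165 lower genes (86.4 in independent lists), with 0 genes called in opposite directions. Both lines were set against the same libraries, so their lists are not independent. The overlap was not counted with split controls. Their fold changes correlated across 14283 genes at 0.578, and at 0.47 with split controls. Pairs of groups drawn at random from the 88 control libraries, each set against the fewer controls left over, correlated at 0.104 on average and at most 0.405. These controls included the Dach1 libraries, of which single ones reached the range of Tbc1d8 for several genes. The covariance of Gsg1l and Tbc1d8 was 0.00774, against 0.000725 on average and at most 0.00355 in the drawn groups. Genes are not independent replicates.

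The names of the libraries hold a middle number that may mark mice of 1 origin. After removing the means of each line and sex, the 18 pairs of 1 line that share it, all of the same sex label, correlated at -0.035, against -0.322 on average when the numbers were permuted within line and sex (permutation p = 1e-04, the smallest 10000 draws can give). The labels do not say what the number means. If such mice are related, p-values that treat all mice of a line as independent are too small. Since each pair carries 1 sex label, this would reach the sex comparisons too.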
